A study of Homo sapiens with 6 samples.

How the data were processed

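DNA-RNA hybrid immunoprecipitation sequencing (DRIP-seq) pulls down DNA that carries an RNA strand (an R-loop) with the S9.6 antibody, after restriction digestion of the nucleic acids, and sequences the sonicated DNA. It was run on SH-SY5Y, a human neuroblastoma line, after lentiviral delivery of 1 of 2 short hairpin RNAs, shT2 or shNC3, and puromycin selection, per the labels' protocols. Each hairpin has 3 samples, named here by hairpin and replicate number. The series concerns TDP-43 knockdown. The labels do not spell out which hairpin targets TDP-43: from the names, shT2 is read here as the knockdown and shNC3 as its negative control, and directions are always given as shT2 relative to shNC3. No label says that the samples of a hairpin came from separately infected cultures. The p-values therefore measure only the spread between these samples, which may be technical, and each hairpin is treated as 1 selected population.

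Each sample has 1 deposited list of narrow peaks, called per sample. The submitters' processing notes name Bowtie2 2.4.4, SAMtools, MACS2 2.2.6 and the genome build hg38. Each deposited list gives the position of a peak, an integer score, the fold enrichment at its summit (a linear ratio over the local background), the −log10 p-value and the −log10 q-value, all as the authors' peak caller wrote them. These per-peak values were used to rank or filter peaks within their own list, and to recover library depth and control background as described below. A fold cut-off need not be equally strict for both hairpins, because the genome-wide background was 2.99 to 3.02 in shT2 and 1.65 to 1.79 in shNC3. The deposited lists hold peaks with a q-value of up to 0.01. The protocols mention an RNase H-treated negative control. Which control entered the peak calling is not given in the sources used here. Positions are those of hg38, printed 1-based.

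Peak rows that shared 1 interval were counted once. Peak number, covered length (the length of the merged peaks) and median width were taken per sample. Peaks were assigned by their midpoint to a gene edge (within 2 kb of either end of a protein-coding or lncRNA gene), a gene body or neither (intergenic), using the RefSeq gene table of GRCh38.p14 with 20033 protein-coding and 18303 lncRNA genes. That table gives no strand and no exons, and no genome sequence was used here. The planned promoter, terminator, exon, intron, repeat-masked and GC shares were therefore not computed, and the gene edge and gene body shares were added in their place after the files had been seen. Overlap between samples was measured as the Jaccard index of covered bases. For shT2 replicate 1 against shNC3 replicate 1, the code used and bedtools 2.31.1 both gave 0.566. Peaks of all samples were merged into regions, and a sample counted as present with an overlap of at least 1 bp.

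For each protein-coding gene, the covered length within the gene span plus 2 kb on each side was scaled to the mean total covered length of the 6 samples. The value log2(scaled covered bp + 500) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust, no covariates), with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes covered in at least 3 of the 6 samples were tested, which left 11769. Log2 differences are on this scale and understate the change of genes with short coverage. A gene with no peak in any sample of a hairpin is described by its levels, with no fold. Covered length says how much of a gene lies under called peaks, not how strong the signal is. Restriction digestion came before the pulldown, so a peak may run to the ends of a cut fragment. Cut sites were not mapped, so covered lengths and widths need not be the extent of an R-loop. The 16 gene lists named in the report were fixed before the data were examined and tested with fry, which asks whether the members of a list move, on balance, in 1 direction. camera, with a preset correlation of 0.01 between genes and with an estimated one, compared each list with the other genes. On simulated values with 200 changed genes in this comparison, run over 11769 genes, limma recovered 19.5% of those changed by 0.5 on the log2 scale, 66.5% of those changed by 1 and 92.0% of those changed by 2. The 200 were drawn from genes with longer mean coverage only. Far more genes were called in the data, where the Benjamini-Hochberg cut-off is less strict, so these shares need not hold there. Single values were compared with a two-sided exact permutation test, which cannot go below p = 0.1 for 3 samples against 3.

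Genes named in the text followed a rule fixed before the data were examined: TARDBP, the 12 genes per direction with the largest log2 difference among those past the threshold whose groups did not overlap, up to 4 members of each list with the smallest p, and the 5 regions per direction with the largest covered width among those present in 3 of 3 samples of 1 hairpin and 0 of 3 of the other. Other genes are named with a remark that they were chosen afterwards. The value of 1 gene that the rule takes is not reported here.

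The lists hold no read counts. Library depth was recovered from them, because MACS2 derives fold enrichment and p from the same pair of numbers, the fragment pileup at the summit and the local background. Both were solved for at the peaks of each list, leaving out any with an extremely small p. Of the peaks tried, 95.4% to 99.9% per list had a single solution. On simulated lists the pileup came back in 100% and 99.4% of peaks. The genome-wide background of a list then gives the mean number of pulled-down fragments per base. For thinning, that number was divided by the shortest peak length of the list, which gave a ratio of means, shT2 over shNC3, of 1.98. Every list was also thinned to the depth of the shallowest library, shNC3 replicate 2, by binomial thinning of the recovered pileups and a repeat of the peak test. For a peak without a solution, the −log10 p was instead taken to shrink with the share of fragments kept. Thinning adds none of the marginal peaks that a truly shallower library would have, so it can understate the number of peaks. A thinned peak keeps its deposited width, so covered length and width can be overstated. Both apply above all to shT2. Equal depth in the text means lists thinned in this way. This alternative was chosen after seeing the data.

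Alternatives fixed beforehand were peaks with a −log10 q of at least 5 or a fold enrichment of at least 5, an equal number of top peaks per list (42717), the main chromosomes only, presence defined by 50% coverage of a region, peaks merged within 1 kb, windows of 1 kb, no scaling, pseudocounts of 100 and 2000 bp, other filters, no flanks, all annotated genes, eBayes without trend and robust, a replicate block, and each sample left out in turn. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.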

Results

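R-loops were mapped in SH-SY5Y neuroblastoma cells that carried the hairpin shT2 (3 samples) or the hairpin shNC3 (3 samples), in a series on the loss of TDP-43, an RNA-binding protein of amyotrophic lateral sclerosis and frontotemporal dementia. The lists held 49068, 50971 and 50821 peaks for shT2 replicates 1 to 3, and 45390, 42717 and 45014 for shNC3 replicates 1 to 3. The pulldown libraries behind them had unequal depth. The recovered depth was 3.31, 3.46 and 3.08 fragments per base in the shT2 libraries and 1.79, 1.65 and 1.74 in the shNC3 libraries, a ratio of means of 1.90.

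The targeted gene itself carried R-loop peaks in every sample. TARDBP, which encodes TDP-43 (chromosome 1, 11012654 to 11030528), was covered over 9702, 9573 and 7819 bp in shT2 replicates 1 to 3 and over 11725, 10554 and 10239 bp in shNC3 replicates 1 to 3. Scaled to total covered length, the means were 8.56 ± 0.87 kb and 11.5 ± 0.68 kb (SD, n = 3 each), a log2 difference of -0.40 (SE 0.09, limma adjusted p = 0.00683). The call was lost without scaling (-0.25, adjusted p = 0.0903) and with peaks of at least 5-fold enrichment (-0.20, adjusted p = 0.430). Neither TDP-43 RNA nor protein was measured here, so this length does not check the knockdown.

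The question of the gene comparison was which genes gain or lose R-loops in the shT2 cells. Some genes were covered over long tracts with 1 hairpin and hardly at all with the other. ALK, the receptor tyrosine kinase mutated in familial neuroblastoma (chromosome 2), was covered over 51.1 ± 1.6 kb in shT2 and 1.68 ± 0.76 kb in shNC3 (SD, n = 3 each). GRIN1, the obligatory NMDA receptor subunit (chromosome 9), was covered over 10.6 ± 0.20 kb against 0.355 ± 0.38 kb, and GFRA2, the co-receptor of neurturin (chromosome 8), over 18.8 ± 1.8 kb against 0.685 ± 0.42 kb. In the other direction, COL5A1, a fibrillar collagen gene (chromosome 9), was covered over 1.60 ± 0.58 kb in shT2 and 62.4 ± 6.5 kb in shNC3, and EPHA2, an ephrin receptor gene (chromosome 1), over 0.621 ± 0.59 kb against 26.5 ± 1.1 kb.

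Of the 12 leading genes with longer coverage in shT2, 4 had no peak in any shNC3 sample: ELAPOR1 (21.3 kb in shT2), the complement gene C7 (11.6 kb), FLRT1 (9.28 kb) and the immune receptor gene CD160 (7.18 kb). The others had short coverage in shNC3. The log2 difference was 4.84 for EXOC4, a subunit of the exocyst, 4.63 for ALK, 4.15 for the metalloprotease gene ADAMTS17, 4.08 for GFRA2, 3.80 for GRIN1, 3.75 for EML5, 3.70 for VSIG10L2 and 3.61 for the growth factor gene FGF17, with limma adjusted p between 8.48e-06 for EML5 and 0.000107 for GRIN1. Some of these loci share peaks with neighbours. LRRC26 next to GRIN1, NPM2 next to FGF17 (no peak in shNC3) and ZC3H14 overlapping EML5 (2.61) were also higher in shT2, and FLRT1 lies within MACROD1 (0.79).

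Of the 12 leading genes with shorter coverage in shT2, 4 had no peak in any shT2 sample: the matrix protein gene LTBP2 (24.6 kb in shNC3), the interleukin receptor gene IL4R (14.8 kb), the keratin gene KRT80 (13.1 kb) and the chemokine gene CXCL12 (12.2 kb). SLC5A10 and FAM83G overlap and shared their peaks, with log2 differences of -5.25 and -5.24. COL5A1 differed by -4.93, the NF-kappa-B subunit gene RELB by -4.77, EPHA2 by -4.76, the Ras GTPase-activating gene RASA3 by -4.71, the semaphorin receptor gene PLXND1 by -4.71 and LSP1 by -4.63. The limma adjusted p of these 8 genes ran from 8.87e-07 for RELB to 0.000113 for EPHA2.

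**Figure D1:**
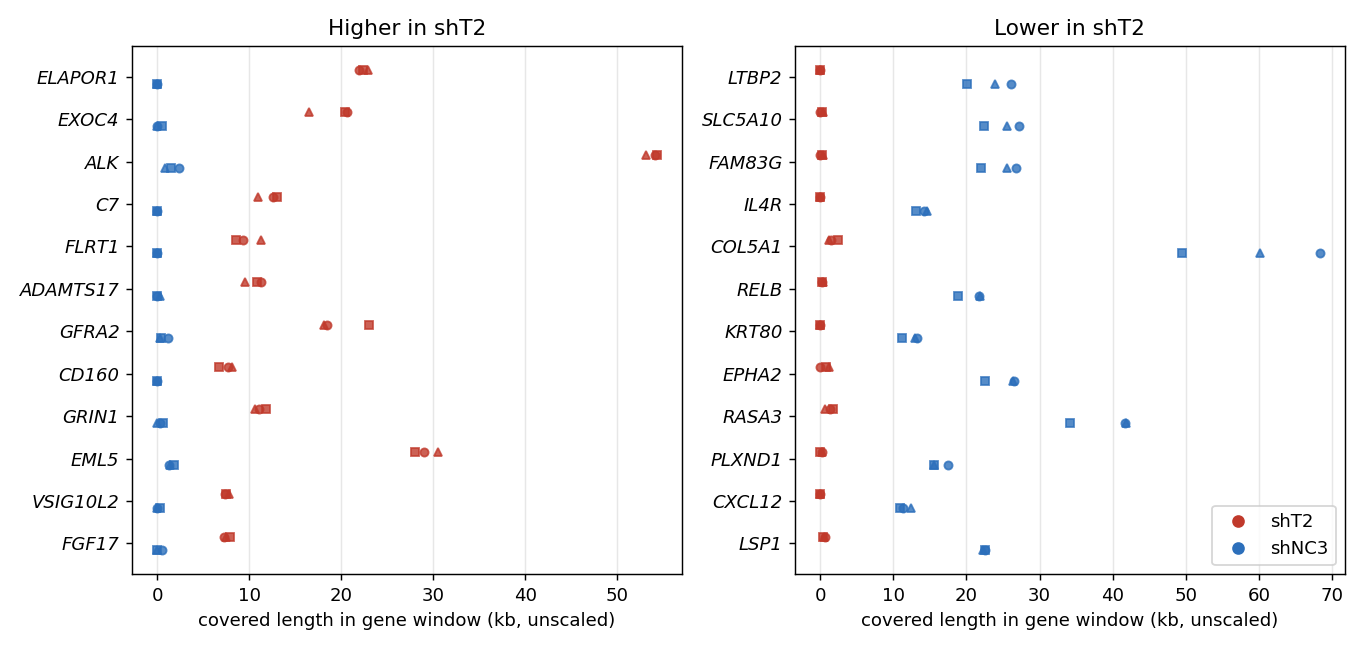
Covered length (kb, unscaled) within the gene window of the 12 leading genes per direction, 1 point per sample, shT2 in red and shNC3 in blue. Marker shapes stand for replicates 1 (circle), 2 (square) and 3 (triangle), and the groups of 3 do not overlap for any of the 24 genes.

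**Figure D2:**
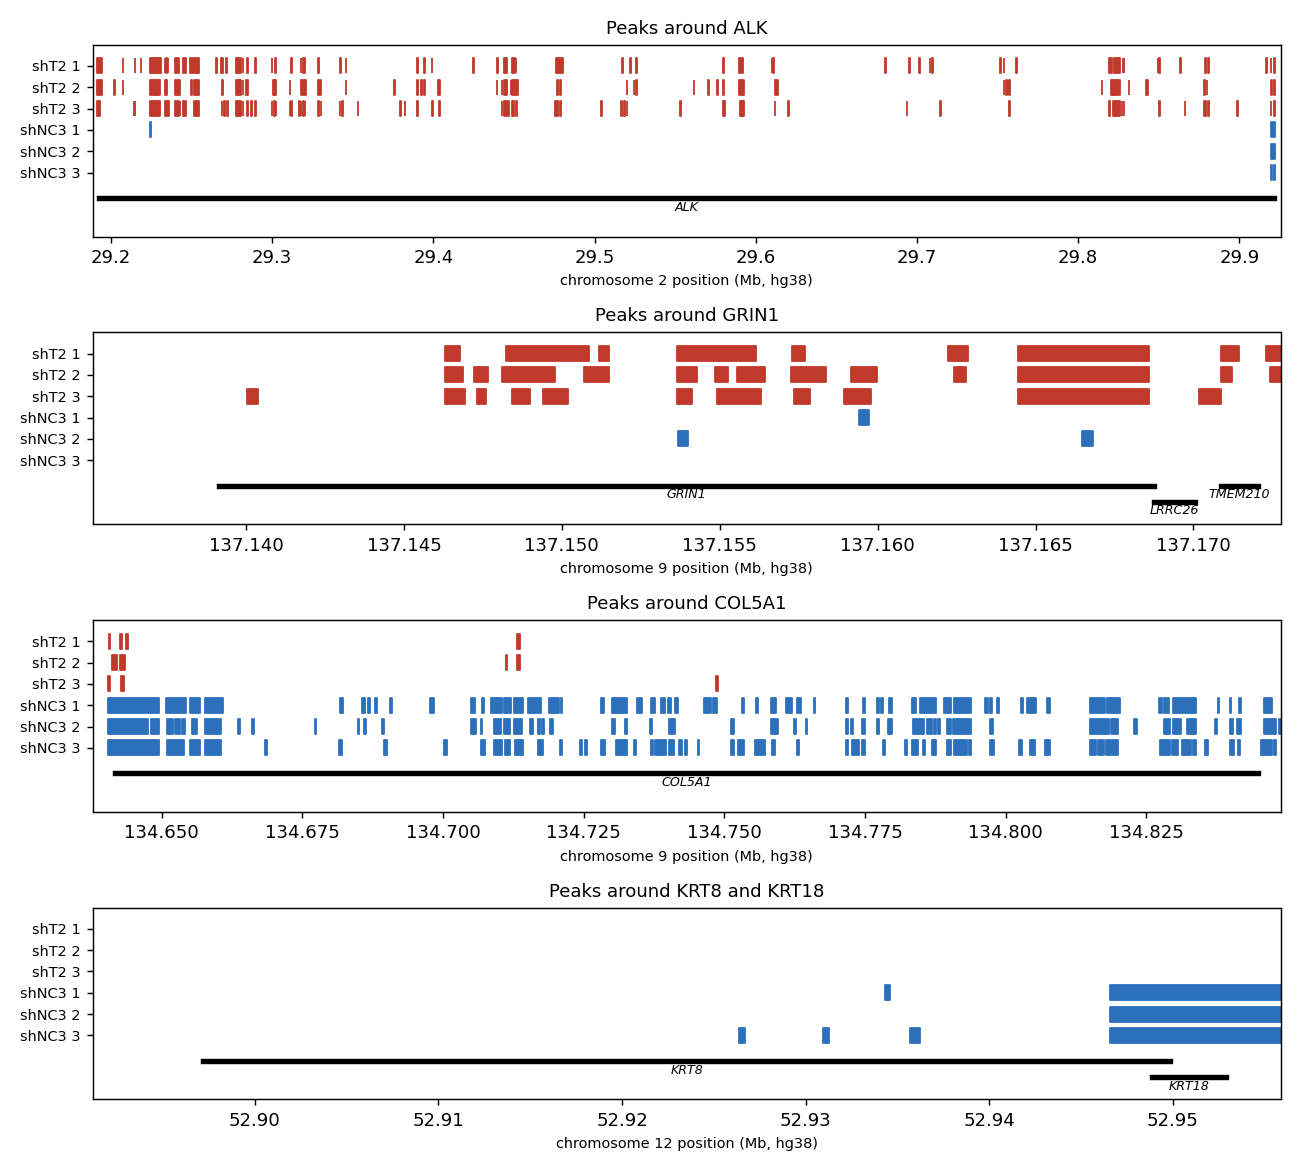
Peaks of each sample (bars) around ALK, GRIN1, COL5A1 and the adjoining KRT8 and KRT18 along hg38, with gene spans in black. Peaks are strung along ALK and GRIN1 in the 3 shT2 samples, and along COL5A1 in the 3 shNC3 samples. At KRT8 and KRT18, the 3 shNC3 samples share a long peak (52946580 to 52956705) over KRT18 and the adjoining end of KRT8. The rest of KRT8 holds few or no short peaks in these samples.

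Across the genome, 2842 genes had longer and 3199 shorter coverage in shT2 at a limma adjusted p under 0.05, of 11769 tested. Of these, 1470 and 1148 differed by more than 1 on the log2 scale. The calls took in 51.3% of tested genes, so a list with like shares of calls does not stand out from the other genes. fry does not make that comparison, and camera does. The 3 values of shT2 and the 3 of shNC3 did not overlap in 65.0% of tested genes, where chance gives 10%. Without scaling to total covered length, 60.9% of called genes were higher in shT2 in place of 47.0%, and the median log2 difference of all genes moved from -0.08 to 0.06. With every list thinned to equal depth, 2365 of the higher and 2610 of the lower genes were called again in the same direction. Counts fell to 1843 higher and 1955 lower with peaks of at least 5-fold enrichment, and to 1572 higher and 2660 lower in windows around the gene ends, where 37.1% of called genes were higher.

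Genes of the mesenchymal neuroblastoma state, the substrate-adherent cell type that such cultures can hold, were on balance covered less in shT2. Of 16 tested members, 9 were lower, none was higher and 7 did not pass (9 lower adjusted over the list alone, median log2 difference -1.19, and -0.59 over the 12 members with a peak in both groups, fry adjusted p = 4.37e-05). With an estimated correlation between genes, camera gave an adjusted p = 0.218. COL1A1 was covered over 0.215 kb in shT2 and 14.3 kb in shNC3 and the galectin gene LGALS1 over 3.06 kb against 8.65 kb, while the transcription factor gene PRRX1 had no peak in shT2 and 3.18 kb in shNC3. The opposing noradrenergic state genes were on balance longer in shT2, with 9 of 17 higher, 2 lower and 6 not passing (the same 9 and 2 over the list alone, median 0.24, fry adjusted p = 0.00491). For this list camera gave an adjusted p = 0.487 when the correlation was estimated. TFAP2B (log2 difference 0.96), the secretory granule gene CHGA (1.06), KLF7 (0.63) and the dopa decarboxylase gene DDC (0.94) were among the higher ones, DDC not in windows around its ends (0.10, adjusted p = 0.844).

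Replication-dependent histone genes that passed were nearly all higher in shT2. Of 55 tested, 23 were higher, 1 lower and 31 did not pass (21 higher and 0 lower adjusted over the list alone, median 0.44, and 0.19 over the 43 with a peak in both groups, fry adjusted p = 4.37e-05). camera with an estimated correlation gave an adjusted p = 0.0942 for the histone list. Of the 23, 22 lie in the histone cluster of chromosome 6 and 11 had no peak in any shNC3 sample. They share peaks in part, with 20 distinct coverage profiles. H2BC12 was covered over 5.26 kb in shT2 and 2.31 kb in shNC3, and H4C5 over 1.62 kb and 0 kb. H2BC13 and H2AC13 lie under the same peaks (1.42 kb and 0 kb).

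Genes whose transcripts carry TDP-43-repressed cryptic exons or polyadenylation sites moved both ways, mostly up: 13 of 22 were higher in shT2, 5 lower and 4 did not pass (13 and 5 over the list alone, median 0.39, fry adjusted p = 0.00231). Under an estimated correlation, camera gave an adjusted p = 0.266. CELF5 (1.14) and SETD5 (0.95) were higher, and the synapse organiser gene AGRN was lower (-1.90). STMN2 (0.64) and UNC13A (1.68), named here after their values were seen because they are the best known TDP-43 splicing targets, were higher. Genes with ALS or FTD mutations went both ways, with 9 of 25 higher, 6 lower and 10 not passing (9 and 6 over the list alone, fry adjusted p = 0.219, and 0.0181 without scaling, median -0.08 and mean 0.11). With the correlation estimated, camera gave an adjusted p = 0.789. ANXA11 was lower (-1.48), and TIA1 (1.31), SPG11 (0.78) and ATXN2 (0.44) were higher. In windows around the gene ends, ANXA11 (-0.70, adjusted p = 0.181) and SPG11 (0.43, 0.135) were not called and ATXN2 changed sign (-0.15, not called).

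Factors that silence transposable elements were on balance longer in shT2: 13 of 26 higher, 4 lower and 9 not passing (13 and 5 over the list alone, median 0.46, fry adjusted p = 0.000181). When the correlation between genes was estimated, camera gave an adjusted p = 0.218. The chromatin remodeller gene SMARCAD1 (1.78), the HUSH subunit gene MPHOSPH8 (1.37), ZNF91 (0.93) and the H3K9 methyltransferase gene EHMT1 (1.24) led them. In windows around the gene ends alone, SMARCAD1 (0.08), ZNF91 (0.38, adjusted p = 0.265) and EHMT1 (0.25, 0.0646) were not called. Zinc finger genes of chromosome 19 went both ways, with 48 of 181 higher, 42 lower and 91 not passing (47 and 41 over the list alone, median 0.13, fry adjusted p = 0.00156). Without scaling, 56 were higher and 30 lower. At equal depth, 40 were higher and 39 lower, with a median of 0.086 (fry adjusted p = 0.0492). Under an estimated correlation, camera gave an adjusted p = 0.218. ZNF43 (1.55) and ZNF253 (2.61) were higher, and ZNF329 (-3.72) and ZNF584 (-1.89) lower, the last not called in windows around its ends (-0.55, adjusted p = 0.154). Of the enzymes and readers of cytosine methylation, 5 of 23 were higher, 6 lower and 12 did not pass (5 and 6 over the list alone, median -0.01, 0.14 without scaling, fry adjusted p = 0.000234, downward). With the correlation estimated, camera gave an adjusted p = 0.927. TET1 (0.73), TET3 (0.54) and the glycosylase gene TDG (0.93) were higher, and the stress gene GADD45B had no peak in shT2 and 6.38 kb in shNC3. The signs of TET1 and TET3 turned in windows around the gene ends (-0.36 and -0.18, neither called), and TDG (1.15, adjusted p = 0.0826) and TET3 (0.19, 0.277) lost their calls at 5-fold enrichment.

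R-loop processing factors were on balance longer in shT2: 14 of 34 higher, 5 lower and 15 not passing (14 and 6 over the list alone, median 0.06, fry adjusted p = 0.00156). When the correlation between genes was estimated, camera gave an adjusted p = 0.335. The counts were 15 higher and 2 lower both at equal depth (median 0.16) and without scaling (median 0.21). The helicase gene DHX9 (1.06) and the RNA editing gene ADAR (0.57) were higher, and the RNase H2 subunit gene RNASEH2A (-1.10) and FANCA (-0.91) lower. DHX9 was not called in windows around its ends (0.35, adjusted p = 0.201). Of the DNA damage response genes, 8 of 25 were higher, 2 lower and 15 did not pass (8 and 2 over the list alone, median 0.15, fry adjusted p = 0.00395). Under an estimated correlation, camera gave an adjusted p = 0.377. PRKDC (1.24), XRCC5 (1.81) and RAD50 (3.02) were higher and the cell cycle inhibitor gene CDKN1A lower (-1.17). In windows around its ends alone, PRKDC was lower in shT2 (-0.90), so its gain lay within the gene body. Nucleic acid sensing and interferon genes had 0 of 10 higher, 5 lower and 5 not passing (0 and 5 over the list alone, median -0.30, and -0.21 over the 8 with a peak in both groups, fry adjusted p = 0.00517). With the correlation estimated, camera gave an adjusted p = 0.418. STAT2 (-0.66, but 0.17 and not called in windows around its ends) and IRF3 (-0.23) were lower, and STING1 and ISG15 had no peak in shT2 and short peaks (0.369 kb each) in shNC3. STAT2 lost its call at 5-fold enrichment (-0.30, adjusted p = 0.130). The other calls were close to the threshold: IRF3 lost its call at equal depth (-0.13, adjusted p = 0.200) and without scaling (-0.08, 0.351), and STING1 and ISG15 when any 1 of the shT2 samples was left out. With a replicate block, IRF3, STING1 and ISG15 were not called (adjusted p = 0.0684, 0.0626 and 0.0723).

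Synaptic genes went both ways, with 8 of 19 higher, 4 lower and 7 not passing (8 and 4 over the list alone, median 0.35, fry adjusted p = 0.00901). When the correlation between genes was estimated, camera gave an adjusted p = 0.432. Besides GRIN1 (3.80), SHANK1 was higher (0.80), and NLGN2 (-0.86) and STX1A (-0.55) were lower, with SHANK1 at -0.14 and not called in windows around its ends. Of the long genes at common fragile sites, 3 of 12 were higher, 3 lower and 6 did not pass (3 and 3 over the list alone, median -0.43, fry adjusted p = 0.000486, downward). Under an estimated correlation, camera gave an adjusted p = 0.487. AUTS2 (0.82) and SDK1 (1.52) were higher, CNTNAP2 was lower (-1.37) and LRP1B had no peak in shT2 and 0.713 kb in shNC3. AUTS2 changed sign in windows around its ends (-0.25, not called), and SDK1 lost its call at 5-fold enrichment (0.71, adjusted p = 0.507).

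Housekeeping groups were mostly not called. Of the cytosolic ribosomal protein genes, 62 of 79 did not pass, 14 were higher and 3 lower (11 and 2 over the list alone, fry adjusted p = 0.688, median -0.07 and mean 0.09). Without scaling, 24 ribosomal protein genes were higher and 1 lower (fry adjusted p = 0.000333, upward, median 0.08). For this list, camera with an estimated correlation gave an adjusted p = 0.927. RPL5 (1.42), RPL37A (0.64), RPL34 (0.59) and RPS26 (0.91) were among the higher. Of the nuclear-encoded oxidative phosphorylation subunits, 50 of 81 did not pass, 17 were higher and 14 lower (15 and 11 over the list alone, fry adjusted p = 0.0123, upward, with a median of -0.02 and a mean of 0.13). Without scaling, 20 were higher and 6 lower, with a median of 0.12. With the correlation estimated, camera gave an adjusted p = 0.487. ATP5F1A (0.87), NDUFA10 (1.36) and NDUFS5 (0.81) were higher and NDUFC2 lower (-2.12), NDUFA10 without a call at 5-fold enrichment (2.39, adjusted p = 0.0604). All 9 loci often used as positive test sites in DRIP had peaks in all 6 samples, and 3 of them were lower in shT2, BTBD19 (-1.18), CALM3 (-0.71) and MYADM (-0.26), with 0 higher and 6 not passing (0 and 3 over the list alone, fry adjusted p = 0.00901, median -0.15), while RPL13A differed by -0.16 (adjusted p = 0.0770). The list was not called with a replicate block (fry adjusted p = 0.0509) or by camera with an estimated correlation (adjusted p = 0.487), and without scaling its median was -0.003.

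**Figure D3:**
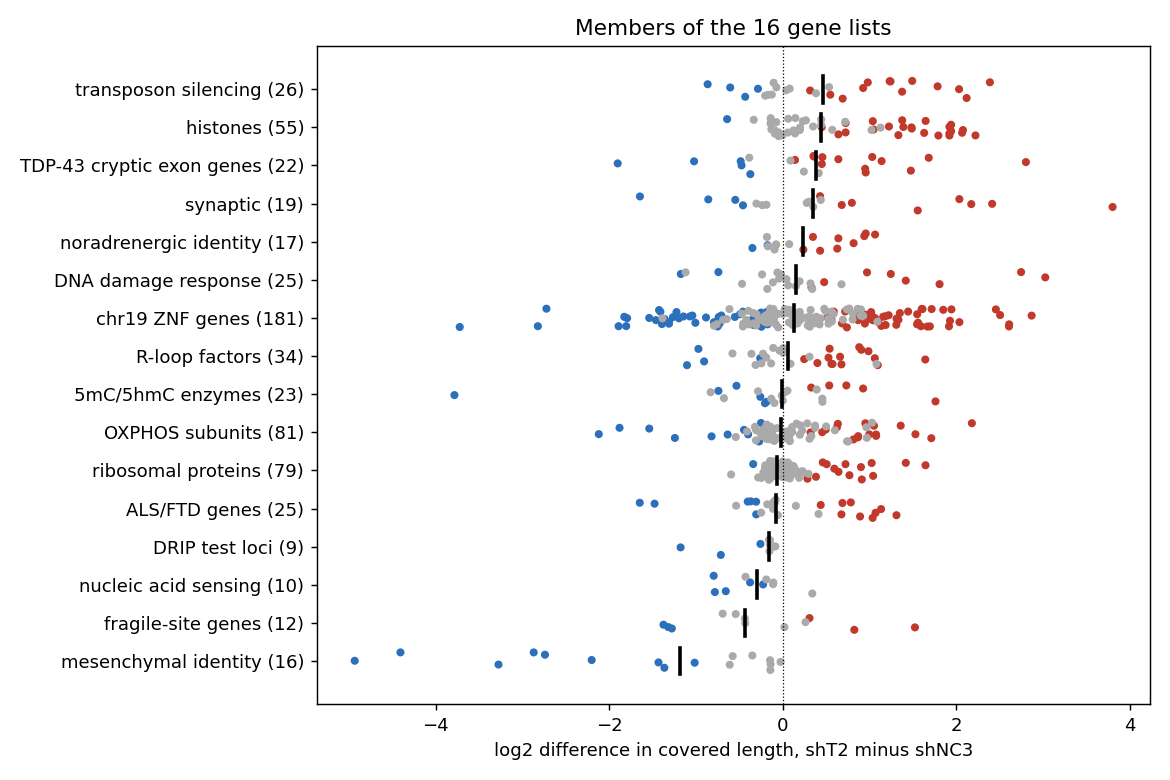
Log2 difference in covered length, shT2 minus shNC3, of every tested member of the 16 lists (number tested in brackets), with the list median as a black bar. Red and blue points passed a limma adjusted p of 0.05 upward and downward, grey points did not; the mesenchymal list has 9 blue and no red points.

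The comparison of sites asked where R-loops were present with 1 hairpin and absent with the other. Widths are those of called regions, whose ends may be set by the restriction digestion, which was not tested. The widest regions found in all 3 shNC3 samples and in no shT2 sample lay at the integrin gene ITGA3 and the lncRNA gene PICART1 (chromosome 17, 50054111 to 50066819, 12709 bp covered in every shNC3 sample), at BCL9L (chromosome 11, 118919578 to 118931813, 10964 ± 567 bp, SD, n = 3), at the keratin genes KRT8 and KRT18 (chromosome 12, 52946580 to 52956705, 10126 bp in every shNC3 sample), in EPHA2 (chromosome 1, 16127911 to 16138473, 9557 ± 1196 bp) and at KRT80 (chromosome 12, 52181296 to 52190927, 8888 ± 900 bp). The widest found in all 3 shT2 samples alone were shorter: at YPEL1 (chromosome 22, 21728752 to 21735506, 6522 ± 203 bp), in an intergenic stretch of chromosome 9 (40880712 to 40886694, 5870 ± 196 bp; nearest gene FOXD4L6, 239740 bp away), at the lncRNA gene PICSAR (chromosome 21, 44995463 to 45001159, 5052 ± 331 bp), at LRRC20 (chromosome 10, 70296274 to 70302330, 5006 ± 447 bp) and in ADAMTS17 (chromosome 15, 100333443 to 100339408, 4923 ± 402 bp).

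In all, 75758 merged regions were found, 15574 of them in all 6 samples, 4447 in 3 of 3 shT2 and 0 of 3 shNC3 samples, and 2170 the other way round. Regions, unlike peaks, were classed by any overlap with a gene edge window, so wider regions reach one more easily. By that rule, regions found in shT2 alone lay at a gene edge in 27.1% of cases and those in shNC3 alone in 39.3%. Those in all 6 did so in 58.9% of cases, and all regions in 32.8%. The median widths were 1078, 1072, 3291 and 605 bp in the same order, so the high share in all 6 may reflect width. The presence of a single region cannot pass an exact test with 3 samples against 3, and no other test was run per region. At equal depth the counts were 2823 and 2595, and among peaks of at least 5-fold enrichment 2096 and 1561.

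Genome-wide, the shT2 lists had 1.13 times as many peaks as the shNC3 lists (50287 ± 1058 against 44374 ± 1447, SD, n = 3 each; exact permutation p = 0.1, the smallest possible). They covered 74.8 ± 2.96 Mb against 67.1 ± 3.89 Mb (exact permutation p = 0.1), a difference of 7.66 Mb that fell to 3.17 Mb at equal depth, where peaks keep their width (p = 0.4), and to 2.86 Mb at 5-fold enrichment (p = 0.3). Fewer of their peaks lay at gene edges, 31.7 ± 0.387% against 34.3 ± 0.587%, and more in gene bodies, 60.2 ± 0.311% against 57.5 ± 0.442% (exact permutation p = 0.1 for each). At equal depth these differences shrank from -2.66 to -1.19 and from 2.70 to 1.34 percentage points (exact permutation p = 0.1 for each). The intergenic share, 8.11 ± 0.102% against 8.15 ± 0.165%, and the median width, 653 ± 28.4 bp against 640 ± 18.5 bp, differed by less than the spread between samples as deposited (exact permutation p = 0.9 and 0.7). Both depended on the peaks taken. The intergenic difference was 0.437 points at 5-fold enrichment (exact permutation p = 0.1), and the width difference ran from -78.3 bp with a −log10 q of at least 5 to 190 bp at 5-fold enrichment (exact permutation p = 0.2 for each). After thinning, 41470 ± 906 peaks were left in shT2 and 43674 ± 829 in shNC3 (exact permutation p = 0.1). Thinning only removes peaks, and it kept 0.456 to 0.517 of the fragments in shT2 and 0.923 to 1 in shNC3, so it lowers the shT2 numbers far more and the new direction decides nothing. With at least 5-fold enrichment the lists differed by 145 peaks (exact permutation p = 0.8). Samples of 1 hairpin shared more covered bases with each other than with the other hairpin's, with mean Jaccard indices of 0.713 within shT2, 0.680 within shNC3 and 0.560 between them. The difference of 0.137 between within-group and between-group overlap exceeded that of the 9 other splits of the samples, the highest of which gave -0.013 (exact permutation p = 0.1).

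**Figure D4:**
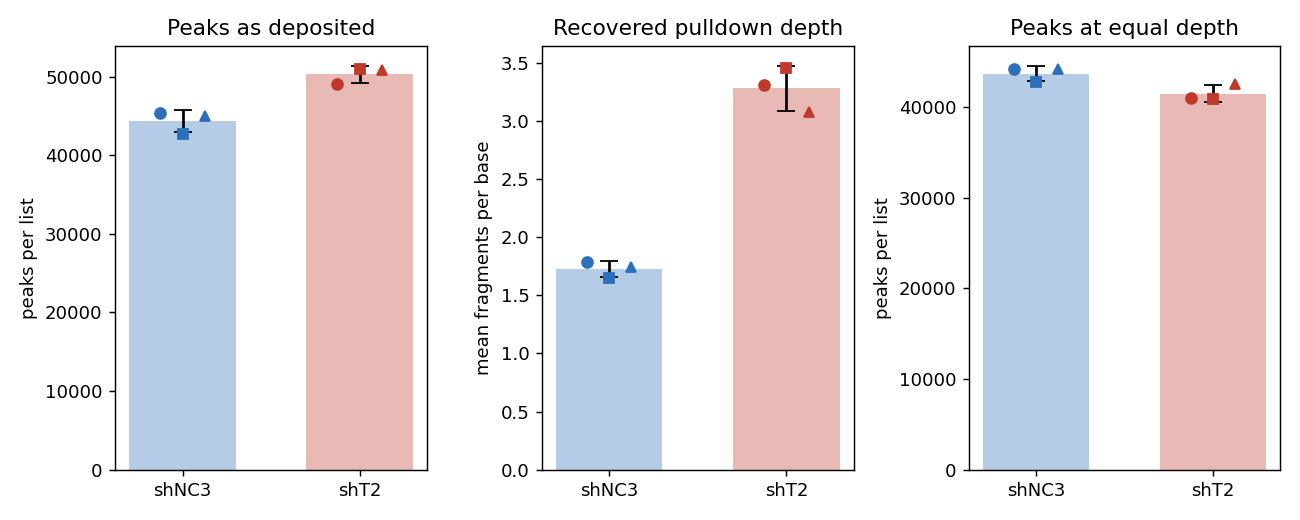
Peaks per deposited list, recovered pulldown depth (fragments per base) and peaks per list at equal depth, with bars for the mean, whiskers for the SD and points for the 3 samples of each hairpin. The shT2 lists hold more peaks as deposited (50287 against 44374 on average) and fewer after thinning, which removes peaks mostly from shT2 (41470 against 43674).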

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

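All tests of this part except the count of splits were chosen after the results had been seen.

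Sequences outside the gene comparisons also differed between the hairpins. On mitochondrial DNA, peaks covered 6.77 ± 0.0758 kb in shT2 and 13.7 ± 0.155 kb in shNC3 (SD, n = 3 each; exact permutation p = 0.1). ND4 was covered end to end in the 3 shNC3 samples and not at all in shT2, CYTB to 100% against 8.38%, and ND2 to 70.0% against 0%, while the rRNA gene RNR1 and ND6 were fully covered in all 6 samples. On the 2 unplaced or unlocalised contigs that carry ribosomal DNA repeats, peaks covered 3.87 ± 0.304 kb in shT2 and 10.2 ± 0.143 kb in shNC3 (exact permutation p = 0.1). The other unplaced or unlocalised contigs went the other way, with 45.4 ± 1.30 kb in shT2 and 29.3 ± 1.92 kb in shNC3 (exact permutation p = 0.1).

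Library depth as the source of the lower coverage of mitochondrial and ribosomal DNA is not settled. The deeper shT2 libraries covered less, with a ratio of mitochondrial covered length of 0.494, where greater depth would mostly add coverage. But depth also set the scaling before peak calling. The pulldown was scaled by 0.866 to 0.982 in shT2, and the control by 0.515 to 0.558 in shNC3. Where pileups no longer rise with depth, such scaling could by itself favour shNC3, which was not tested. The copy number of these sequences stays open too. The ratio for ribosomal DNA was 0.379, and because the same control library seems to stand behind all 6 lists, a copy number difference between the lines could not have been corrected and cannot be told apart from a change in R-loops. A biological effect of the hairpin on these loci is untested.

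The larger number of peaks in shT2 may come from sequencing depth, which stays open. Thinned to the depth of the shallowest library, the mean difference in peaks, shT2 minus shNC3, was -2204, where the deposited lists gave 5913. Thinning only removes peaks and did so mostly in shT2, which pushes this value down, so depth and an effect of the hairpin on peak number cannot be told apart. The tables argue against a separate control library for each hairpin: at summits shared between a shT2 and a shNC3 list the control background was equal (within 0.03 fragments) in at least 79.3% of cases, where independent libraries would give at most 17.4%. Between lists of 1 hairpin the share was higher, 90.7% to 97.8%, and what lowers it between hairpins was not tested. An effect of the hairpin on the total amount of R-loops stays untested, since peak lists cannot show one.

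Greater depth would mostly add coverage, which goes against depth as the source of the lower coverage of mesenchymal genes in shT2. Without scaling to total covered length, the median log2 difference of the list was -1.04, with 9 members lower and 0 higher. The deeper libraries are thus those with less coverage. But depth also set the scaling before peak calling, and its effect on these genes was not tested, so depth is not excluded. A share of mesenchymal cells in the shNC3 culture stays open as a candidate explanation, from a list fixed before the data were examined, since 9 members were lower in shT2 and 0 higher. Abundant members of that state did not all move: VIM differed by -0.15 (covered in all 6 samples, not passing) and FN1 by -0.58 (limma adjusted p = 0.0717). The culture, the cell state and the hairpin cannot be told apart, because no label says that a hairpin stands for more than 1 selected population.

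The count of genes called in the real grouping, 6041, came from 1 of the 10 ways to split the 6 samples. The highest count of the 9 other splits was 0, but 10 splits are too few for a share under 0.05.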

How the results depend on the processing

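Alternatives at equal depth, in windows around both gene ends and with other annotations for the shares of peaks were chosen after seeing the data. At equal depth the difference in peak number turned from 5913 to -2204, a setting that removes peaks mostly from shT2. With a −log10 q of at least 5, the difference in median width was -78.3 bp and that in intergenic share 0.434 percentage points. The width difference was 12.3 bp as deposited, 113 bp with an equal number of top peaks, 126 bp at equal depth, where short peaks leave mostly the shT2 lists, and 190 bp with at least 5-fold enrichment. With at least 5-fold enrichment, the intergenic difference was 0.437 points, regions in shT2 alone numbered 2096, and 1843 genes were higher and 1955 lower. With all annotated genes the intergenic difference was 0.114 points. Regions in shT2 alone numbered 2823 at equal depth, and regions in shNC3 alone 1423 when peaks within 1 kb were merged. Without scaling 2044 genes were lower, and in windows around the gene ends 1572 were higher and 2660 lower. The cause of these changes was not tested. In those windows, which leave out gene bodies, ATXN2 (-0.15), TET1 (-0.36), TET3 (-0.18), SHANK1 (-0.14), AUTS2 (-0.25), PRKDC (-0.90) and STAT2 (0.17) changed sign. Of the 16 lists, 14 passed with fry, 2 (histones and mesenchymal) with camera at the preset correlation and 0 with camera at an estimated correlation, which ask a different question. With a replicate block 13 passed with fry, without the DRIP test loci.

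Leaving out 1 sample at a time gave 5072 to 6873 regions in shT2 alone and 2534 to 3823 in shNC3 alone, more because fewer samples have to meet the rule. It gave differences in width of -0.333 to 27.7 bp and in intergenic share of -0.134 to 0.0169 points, 2100 to 2745 genes higher and 2346 to 2717 lower. It also gave differences of -2.91 to -2.34 points in gene edge share, 2.47 to 2.91 in gene body share, 5.53 to 9.34 Mb in covered length, 5085 to 6522 in peak number and 0.128 to 0.147 in replicate overlap. Over the other alternatives these ran from -3.85 to -1.19 points, 1.20 to 3.42 points, 2.86 to 9.0 Mb, -2204 to 8439 peaks (145 at 5-fold enrichment) and 0.135 to 0.156. All kept their direction except the peak number at equal depth. Pairs of a gene and an alternative were counted only where the gene passed the coverage filter of that alternative. Leading genes covered in 1 hairpin alone were thus not counted when at least 5 of 6 samples had to be covered. Nor were they counted when 1 of their covered samples was left out. Of 465 counted pairs of a leading gene and an alternative, 465 kept the call. Of 1745 counted pairs over all 87 named genes, 1699 kept it, 37 lost it, 2 gained it and 7 changed sign.

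Same-numbered samples did not deviate together (correlations -0.02, -0.06 and -0.01). With a replicate block, 2824 genes were higher and 2866 lower, and the peak number difference was 5913 (exact sign-flip p = 0.25, the smallest possible). Not run, for want of strand, exons and sequence, were the promoter, terminator, exon, intron, repeat-masked and GC shares and the promoter window. Depth limits the shNC3 lists most: a gene listed there without a peak may hold one below the threshold, and 2823 in place of 4447 regions remained in shT2 alone at equal depth.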

Other observations

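The 13 families below were taken by gene symbol and picked after the table of genes had been seen, so their tests describe the same data they were picked from, and no explanation is offered. Most tested members of 5 families were covered less in shT2. Of the S100 calcium-binding genes 7 of 7 were lower, among them S100A6 (-2.68), S100A1 (-1.27) and S100A13 (-0.87), with no peak in shT2 for S100A10, S100A11 and S100A16. S100A1 lies within S100A13, and the windows of S100A5 and S100A6 overlap, so these genes share peaks and the 7 are not separate loci. Of the annexins 5 of 7 were lower and 0 higher, with ANXA2 (-2.71) and ANXA6 (-1.20). Of the plexins, the semaphorin receptors, 6 of 8 were lower and 0 higher, with PLXNA3 (-1.84) and PLXNA4 (-2.52) besides PLXND1. Of the integrins 9 of 15 were lower and 2 higher, with no peak in shT2 for ITGB5, ITGA5, ITGB6 and ITGB3, and ITGB1 higher (0.48). Of the collagens 12 of 21 were lower and 1 higher, with COL7A1 (-2.13). The camera adjusted p at the preset correlation was 0.00242 for S100, 0.0150 for annexins, 0.00355 for plexins, 0.0260 for integrins and 0.00355 for collagens, and at an estimated correlation the adjusted p was 0.173, 0.173, 0.173, 0.209 and 0.173.

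Other families had more members higher than lower in shT2. Of the genes with EIF symbols, translation initiation factors and some of their regulators, 25 of 51 were higher, 5 lower and 21 did not pass, with EIF2S2 (0.96), EIF2B1 (2.11) and EIF3M (1.50), and no peak in shNC3 for EIF5B. Of the ubiquitin-specific proteases 16 of 42 were higher, 4 lower and 22 did not pass. Of the SR splicing factors 6 of 12 were higher, 0 lower and 6 did not pass, with SRSF3 (0.74) and SRSF7 (0.81), and of the hnRNP genes 9 of 20 were higher, 1 lower and 10 did not pass, with HNRNPH2 (1.94) and HNRNPC (1.18). DEAD-box genes had 14 of 31 higher and 5 lower, and genes with PSM symbols, mostly of the proteasome, 20 of 43 and 11. At equal depth, 13 of the PSM genes were higher and 9 lower. In the order given, the camera adjusted p at the preset correlation was 0.00355, 0.0120, 0.0249, 0.0325, 0.0430 and 0.128, and at an estimated correlation it was 0.173, 0.219, 0.173, 0.247, 0.219 and 0.209. SLC transporters, with 51 of 225 higher and 72 lower, and KCN genes, with 10 of 37 and 10, were split (camera adjusted p = 0.640 and 0.957 at the preset correlation).

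Chromosome 19 held 8.31 ± 0.0288% of shT2 peaks and 9.71 ± 0.233% of shNC3 peaks (SD, n = 3 each; exact permutation p = 0.1), and 8.53% against 9.74% at equal depth.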
